A study of Mus musculus with 7 samples.

How the data were processed

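RNA in formalin-fixed liver sections of 24-week-old mice was measured with the GeoMx mouse whole transcriptome assay in 6 regions chosen by Albumin staining and not marked by CLEC4F, 3 from NCD and 3 from FFD mice. The series text states 3 mice per diet, and the labels do not tie a region to a mouse. All 6 regions lay on 1 slide, so no slide term was fitted. The no template control was not analysed here.

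The deposited count table, after probe quality control, holds expected counts per target, whole numbers for all but 4 targets that combine several probes. The series text calls them molecule counts, and their sums exceed the deduplicated reads of the segment table in the FFD regions. A deposited filtered table holds the same expected counts for 13099 of 19963 targets. In 1 cell, 1700001K19Rik in FFD 2, it gives 75 where the full table gives 49. The rule of that filter is not stated. The deposited Q3 table holds a signal, the filtered counts of each region divided by its 75th percentile and multiplied by 1 constant, which matched within 0.104% when recomputed. Nuclei and sequencing reads are counts per the file headers, and sequencing saturation is a percent per the file headers, from 99.1 to 99.3. Area, slide position, probes per target and the limit of quantitation are other quantities per the file headers, and their units or formula are not stated. GRCm38 and edgeR are named in the submitters' processing notes without versions or roles.

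Counts were tested for the 13095 genes of the filtered table, leaving out 4 of its 13099 targets that are not genes. The full table holds 12 such targets (negative probes and reporters), with 0.0145 to 0.0192% of counts per region. Counts of 3 tested genes that were not whole were rounded. Targets that several genes share are named by 1 of them, and 169 called targets are of this kind. Gene IDs were matched to the RefSeq table of GRCm38.p6 for coordinates (13074 of 13095 matched). The test was edgeR 4.0.16 quasi-likelihood (glmQLFit, glmQLFTest) under R 4.3.3, with upper quartile scaling at the 75th percentile, diet as the only term and Benjamini-Hochberg adjustment over all tested genes at 0.05. The biological coefficient of variation was 12.0%. Levels are counts scaled to CPM by edgeR's cpm function on the scaled library sizes. Log2 fold changes are FFD over NCD, and n is 3 regions per diet. The standard error (SE) given with them is approximate, the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Counting error and depth are set by 2069102 to 3491371 counts per region.

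In total 46 gene lists were fixed by name, and 45 with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, adjusted over the 45 lists. The same lists were run with an estimated correlation and with fry. For each list the members past the threshold were also counted with p adjusted over the list alone. The list names are: cholesterol synthesis, fatty acid synthesis, lipid droplet, fatty acid oxidation, bile acid, sterol export and LXR, lipoprotein, secreted plasma proteins, transcription factors, periportal, pericentral, gluconeogenesis, glycolysis, urea cycle, male-biased, female-biased, drug metabolism, NRF2, ER stress, integrated stress response, p53, cell death, acute phase, complement, interferon, class I, NF-kB, oxidative phosphorylation, biogenesis, ribosome, proteasome, lysosome, cell cycle, clock, iron, hepatokines and fatty liver or progenitor genes, and markers of Kupffer cells, monocyte-derived macrophages, stellate cells, endothelium, cholangiocytes, lymphocytes, neutrophils, MHC class II cells and erythroid cells. Target groups from the deposited annotation were not tested because it holds filter groups only.

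Named genes followed a rule. Among genes past the threshold, without overlap between the diets and with a mean count in the higher diet above the detection limit, the 12 largest rises and 12 largest falls were named. From each list up to 4 members with the smallest p past the threshold were named in order of p, or the first 2 as values where none passed, and Alb always. Some genes that this rule picked are not reported here. The detection limit was 2 times the negative probe level of the region. Region measures were compared by exact two-sided permutation tests of the difference of means. No paired analysis was possible because the labels number the regions 1 to 6 and share no number between the diets. Groups of 3 were not tested for single deviating regions.

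The comparisons, lists, naming rule and alternatives were set before the data were examined, except where stated. The alternatives were TMM, DESeq2 size factors, total counts or negative probes for scaling, the DESeq2 1.42.0 Wald test, limma trend on the deposited Q3 signal, limma voom, edgeR's robust option, no filter, filterByExpr, genes above the detection limit in 3 regions, subtraction of the negative probe level with values under 1 set to 1, adjusted p under 0.1, an absolute log2 fold change over 1, and each region left out in turn. Detection limits of 1.5 times the negative probe level and of 10 counts were tried. Chosen after seeing the data were the deposited limit of quantitation, NCD 1 and NCD 2 summed as 1 sample, and FFD 3 as the only FFD region.

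The procedure was tested on simulated data with 200 changed genes among 13095. It recovered 37.3% of changes of 1.5-fold, 97.0% of 2-fold and 100% of 4-fold changes, 4.88% of its calls were false, and it made 2 calls in data with no change. The changed genes were drawn only from genes over a set mean count, so the recovered shares do not cover genes with lower counts. Rises and falls were about equal in number and the spread was that of the fit itself. The share of false calls therefore does not cover errors from the choice of scaling.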

Results

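RNA was measured in 6 Albumin-positive areas of fixed liver sections from 24-week-old mice, 3 areas from mice on the NCD diet and 3 from mice on the FFD diet. The diet names are given here as the labels give them. The assay was the GeoMx mouse whole transcriptome probe set, in which a bar-coded probe bound to each transcript in a chosen area is released by light and counted by sequencing. Total counts over the 13095 tested genes were 2069102, 2417342 and 3491371 in NCD regions 1 to 3. In FFD regions 1 to 3 they were 2484982, 2980613 and 2527499. The no template control was not analysed here.

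Several measures of the regions themselves did not overlap between the diets. NCD regions held 1818 ± 106 nuclei (SD, n = 3) and FFD regions 1194 ± 102, with areas of 503548 ± 6837 and 427239 ± 16437 in a unit that the files do not state. In NCD regions 8146 ± 195 genes lay above the detection limit, which was 2 times the negative probe level, and in FFD regions 9468 ± 934. FFD regions 1 to 3 had 9090, 10532 and 8782 such genes. Their sums of target counts over deduplicated reads were 1.20, 1.51 and 1.01, in the same order of size. Without FFD 2 the gain in FFD was 790 genes in place of 1322. Whether the excess of counts over reads raised these numbers was not tested. Albumin (Alb), whose staining chose the regions, made up 6.48 ± 1.11% of counts in NCD regions and 3.67 ± 1.10% in FFD regions. The 10 most abundant genes together took 16.7% of counts in NCD regions and 11.6% in FFD regions. The negative probe level was 0.252 ± 0.0120 of the upper quartile count in NCD regions and 0.193 ± 0.0184 in FFD regions. For each of these measures the NCD and FFD values did not overlap, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows (adjusted p 0.2 over 18 measures). Total counts did not separate the diets (exact permutation p = 1).

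**Figure D1:**
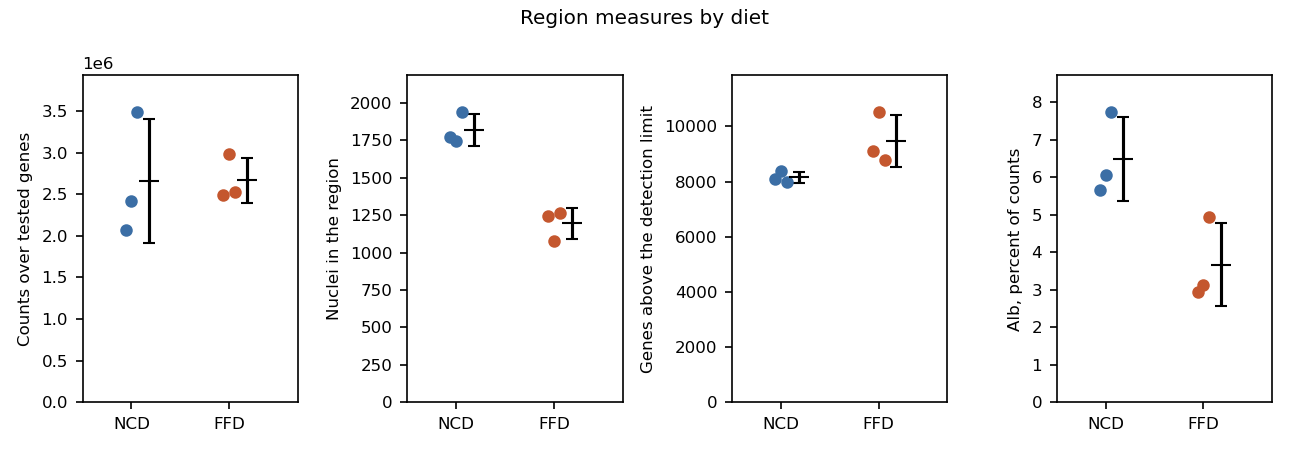
Counts over tested genes, nuclei, genes above the detection limit and Alb as a percent of counts in each region (points), with the mean and SD of each diet (bars, n = 3). Nuclei averaged 1818 in NCD and 1194 in FFD regions, and the counts overlapped.

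The comparison of FFD with NCD asked which hepatocyte transcripts differ between mice on the 2 diets. Genes that rose in FFD included Apoa4, of lipid transport, Cidec and Cd36, of fat storage, Lcn2 and Saa1, of the acute phase, the collagens Col1a1 and Col3a1, and the macrophage elastase Mmp12. Genes that fell included the male-biased Hsd3b5, the cytochrome P450 gene Cyp2c29 and Cyp51, of cholesterol synthesis. Of the 26 gene lists called with a preset correlation, 0 kept the call with an estimated one, including lists whose estimated correlation was below the preset one. Without background subtraction, the largest rise was in Apoa4, an apolipoprotein, from 55.2 ± 5.72 to 3179 ± 1875 CPM (upper quartile scaled counts, SD, n = 3 in each diet). The largest fall was in Hsd3b5, a steroid dehydrogenase of male mouse liver, from 314 ± 27.2 to 16.9 ± 2.98 CPM. Of 13095 genes, 778 rose and 1459 fell in FFD (edgeR, adjusted p under 0.05), and 162 of the risen and 120 of the fallen genes changed more than 2-fold.

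Apoa4 (gene ID 11808, GRCm38 chromosome 9, 46240844 to 46243458) had a log2 fold change of 5.85 (SE 0.37, adjusted p 7.76e-08), or 57.5-fold. Lcn2, an iron-chelator binding protein of the acute phase (chromosome 2, 32384637 to 32387739), rose 15.4-fold (log2 3.95, SE 0.17, adjusted p 8.19e-10). Its NCD level of 10.8 ± 1.62 CPM lay under the detection limit in all NCD regions, so background is part of that level. With background subtracted the log2 change was 8.59, but values under 1 were set to 1 there. The 8.59 therefore rests on this floor and is no measured size of change. Background-subtracted values given below for genes under the detection limit can depend on the floor in the same way. Mmp12, a macrophage elastase, rose by 3.69 (SE 0.40) and Spp1, which encodes osteopontin, by 3.68 (SE 0.45). Saa1 and Saa2, the serum amyloid A proteins, rose by 3.43 (SE 0.22) and 3.15 (SE 0.20). The fibrillar collagens Col1a1 and Col3a1 rose by 3.28 (SE 0.33) and 3.04 (SE 0.28), and Cidec, a lipid droplet protein, by 2.98 (SE 0.24). The metallothioneins Mt2 and Mt1, which bind zinc, rose by 2.72 (SE 0.48) and 2.50 (SE 0.45). A target shared by 6 predicted genes and listed under LOC118568705 rose by 2.71 (SE 0.31). Mmp12 and Col1a1 were under the detection limit in all NCD regions and Cidec above it in 1 of 3. With background subtracted they stood at 7.08, 5.28 and 5.06, sizes that can depend on the floor of 1. With FFD 3 as the only FFD region Spp1 stood at 1.90, Col1a1 at 2.12 and Col3a1 at 2.06, and Mmp12 at 4.51. Spp1 was at 830, 953 and 193 CPM in FFD regions 1 to 3, and its adjusted p was 0.0479 with edgeR's robust option (range over the alternatives 1.67e-09 to 0.0479). Without FFD 3 the log2 change of Mt2 was 1.74, that of Mt1 1.57 and that of Mmp12 3.01, and the calls of Mt2 and Mt1 were lost with edgeR's robust option (adjusted p 0.114 and 0.117).

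Hsd3b5 (gene ID 15496, chromosome 3, 98618636 to 98645534) fell 18.5-fold (log2 -4.21, SE 0.17, adjusted p 8.19e-10). It lay above the detection limit in 1 of 3 FFD regions, so background is part of its FFD level, and the log2 change was -5.69 with background subtracted. The target listed under Mup13, which 16 major urinary protein genes share, went from 27992 ± 6106 to 1670 ± 764 CPM (log2 -4.07, SE 0.36). Slco1a1, an organic anion transporter of the hepatocyte membrane, fell 12.5-fold (log2 -3.64, SE 0.29, adjusted p 8.51e-07). Cyp2c29 and Cyp2c50, P450 enzymes of drug and fatty acid metabolism, fell by 3.03 (SE 0.22) and 2.68 (SE 0.15). Sult2a8, a bile acid sulfotransferase, fell by 3.00 (SE 0.27) and Cyp7b1, an oxysterol hydroxylase, by 2.91 (SE 0.15). Etnppl, which breaks down phosphoethanolamine, fell by 2.77 (SE 0.28). Ces2a, a carboxylesterase, fell by 2.31 (SE 0.15), and Enho, which encodes the peptide adropin, by 2.20 (SE 0.14). Elovl3, a fatty acid elongase, fell by 2.17 (SE 0.19) and Cyp51, a sterol demethylase, by 2.15 (SE 0.22). Elovl3 lay under the detection limit in all FFD regions, Cyp51 above it in 1 of 3 and Enho in 2 of 3, and with background subtracted they stood at -4.28, -3.15 and -2.93. With FFD 3 as the only FFD region Mup13 stood at -4.92, Slco1a1 at -4.67 and Sult2a8 at -3.97.

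**Figure D2:**
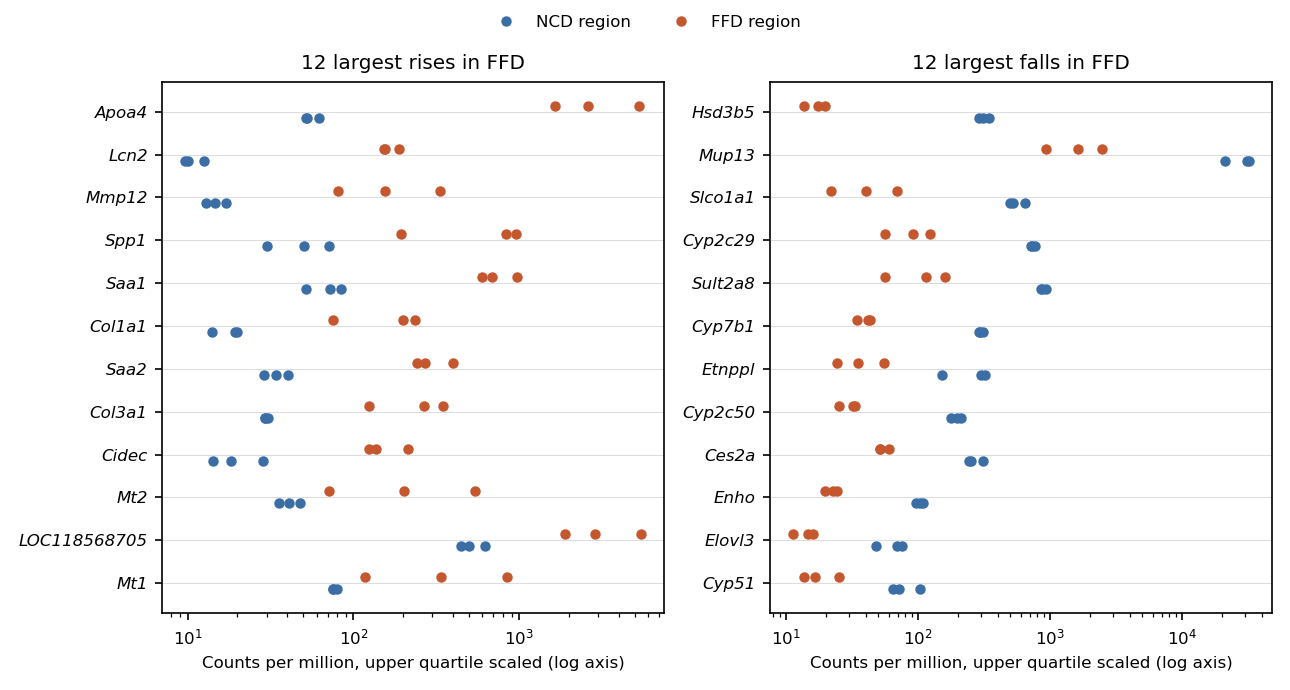
Upper quartile scaled CPM (log axis) of the 12 largest rises and the 12 largest falls, 1 point per region. Apoa4 averaged 55.2 in NCD and 3179 in FFD regions, and Hsd3b5 314 and 16.9.

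In the lipid droplet list 10 of 15 tested genes rose and none fell (12 higher adjusted over the list alone, camera adjusted p 8.56e-12, adjusted p 0.138 with an estimated correlation). The fatty acid transporter Cd36 rose by 2.45 (SE 0.15), Cidec by 2.98, the droplet coat protein Plin4 by 1.66 (SE 0.16) and the lipid carrier Fabp4 by 1.29 (SE 0.16). Plin4 lay under the detection limit in all NCD regions and stood at 5.55 with background subtracted, a size that can depend on the floor of 1. Fatty acid oxidation genes and PPAR alpha targets also rose, 11 of 21 (12 adjusted over the list alone, camera adjusted p 1.67e-09, adjusted p 0.221 with an estimated correlation). They included the fatty aldehyde dehydrogenase Aldh3a2 at 1.66 (SE 0.15), the pantetheinase Vnn1 at 1.36 (SE 0.15) and Cpt1a, which admits fatty acids to mitochondria, at 0.97 (SE 0.14). Among sterol export genes and LXR targets 4 of 12 rose (7 adjusted over the list alone, camera adjusted p 3.65e-05, adjusted p 0.221 with an estimated correlation), led by the desaturase Scd1, higher 2.83-fold (SE 0.31 on the log2 scale), and the sterol exporter Abcg1 at 0.79 (SE 0.18). Glycolysis and fructose genes rose in 6 of 18 cases (9 adjusted over the list alone, camera adjusted p 5.31e-07, adjusted p 0.221 with an estimated correlation), among them the pyruvate kinase Pkm at 0.88 (SE 0.16) and the aldolase Aldoa at 0.82 (SE 0.16). In the same FFD regions 8 of 15 Kupffer cell genes (adjusted p 0.323 with an estimated correlation) and 9 of 10 lipid-associated macrophage genes (adjusted p 0.107 with an estimated correlation) were higher.

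Cholesterol synthesis genes fell, 19 of 24, and none rose (21 lower adjusted over the list alone, camera adjusted p 1.69e-11, adjusted p 0.323 with an estimated correlation). The sterol oxidase Msmo1 fell by 2.07 (SE 0.15), Cyp51 by 2.15, the sterol reductase Tm7sf2 by 1.54 (SE 0.16) and the isomerase Idi1 by 1.39 (SE 0.16). The fatty acid synthesis list was split, with 3 higher, 3 lower and 14 of 20 not past the test (3 and 3 adjusted over the list alone, camera adjusted p 0.814, adjusted p 0.960 with an estimated correlation). Lipoprotein genes were also split, with 2 higher, 2 lower and 14 not past the test (4 and 3 adjusted over the list alone, camera adjusted p 0.0584, adjusted p 0.669 with an estimated correlation). Apoa4 and Apoc2, which activates lipoprotein lipase, rose by 5.85 and 1.52 (SE 0.18), and Apom, the carrier of sphingosine phosphate, fell by 1.39 (SE 0.19). The lipoprotein list passed as higher without a filter (adjusted p 0.00354), with filterByExpr (0.00353), and without FFD 1 (adjusted p 0.0284), FFD 2 (0.0233) or NCD 3 (0.0205), and with FFD 3 as the only FFD region (0.00191). Gluconeogenesis and glycogen genes gave 4 higher and 2 lower of 16 (4 and 3 adjusted over the list alone, camera adjusted p 0.379, adjusted p 0.721 with an estimated correlation). The glucose phosphatase G6pc fell by 1.28 (SE 0.18) and the tyrosine aminotransferase Tat by 1.27 (SE 0.21), while pyruvate carboxylase, Pcx, rose by 0.91 (SE 0.18).

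Bile acid genes fell in 9 of 19 cases and 1 rose (9 lower and 2 higher adjusted over the list alone, camera adjusted p 0.00849, adjusted p 0.323 with an estimated correlation). Besides Cyp7b1 and Slco1a1, the bile acid importer Slc10a1 fell by 1.48 (SE 0.17) and the bile salt export pump Abcb11 by 0.89 (SE 0.14). The list's call was lost without NCD 3 (adjusted p 0.0838). Drug-metabolising enzymes fell in 9 of 17 cases and 1 rose (10 lower and 1 higher adjusted over the list alone, camera adjusted p 0.00117, adjusted p 0.221 with an estimated correlation). Cyp2c37 fell by 1.97 (SE 0.21) and Aox3, an aldehyde oxidase, by 1.96 (SE 0.22). Male-biased liver genes fell in 9 of 10 cases (9 adjusted over the list alone, camera adjusted p 6.67e-13, adjusted p 0.107 with an estimated correlation), and Susd4, a complement regulator, fell by 2.05 (SE 0.18, under the detection limit in all FFD regions and -4.18 with background subtracted) beside Hsd3b5, Cyp7b1 and Slco1a1. Female-biased genes gave 0 higher and 3 lower of 10 (4 lower adjusted over the list alone, camera adjusted p 0.110, adjusted p 0.669 with an estimated correlation). That list passed without NCD 3 (adjusted p 0.0276) or FFD 3 (0.0273), and the first of its fallen members, Cyp3a41a at -0.91 (SE 0.17), shares its target with 4 other Cyp3a genes.

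Pericentral hepatocyte genes fell in 6 of 16 cases and 1 rose (7 lower and 1 higher adjusted over the list alone, camera adjusted p 0.00145, adjusted p 0.344 with an estimated correlation). The glutamate transporter Slc1a2 fell by 2.09 (SE 0.18) and the P450 enzyme Cyp1a2 by 1.88 (SE 0.22, at -2.67 with FFD 3 as the only FFD region). Periportal genes gave 3 higher and 3 lower of 17 (4 and 5 adjusted over the list alone, camera adjusted p 0.938, adjusted p 0.981 with an estimated correlation), with Etnppl lower and the aldehyde dehydrogenase Aldh1b1 higher by 1.71 (SE 0.27, call lost with edgeR's robust option at adjusted p 0.0607). With FFD 3 as the only FFD region Aldh1b1 stood at 2.36 and the periportal list passed as higher (mean shift 0.43, adjusted p 0.000775). Urea cycle and amino acid genes gave 1 higher and 7 lower of 25 (1 and 10 adjusted over the list alone, camera adjusted p 0.139, adjusted p 0.772 with an estimated correlation), with Tat lower and Mat1a, which makes the methyl donor S-adenosylmethionine, higher by 0.86 (SE 0.17). The urea cycle list passed as lower without NCD 1 (adjusted p 0.0117) or FFD 3 (0.00148) and with NCD 1 and NCD 2 summed (0.0345). Secreted plasma protein genes fell in 7 of 22 cases and 2 rose (10 lower and 2 higher adjusted over the list alone, camera adjusted p 0.0259, adjusted p 0.725 with an estimated correlation). Cp, the copper carrier ceruloplasmin, rose by 0.85 (SE 0.15) and Plg, plasminogen, fell by 0.82 (SE 0.17, adjusted p 0.119 with negative probe scaling and 0.0908 with FFD 3 as the only FFD region). This list's call was lost without NCD 3 (adjusted p 0.382), FFD 1 (0.191) or FFD 2 (0.0823) and with FFD 3 as the only FFD region (0.780). Alb itself was at -0.93 (SE 0.33, adjusted p 0.0648). It passed as lower in 4 of 20 alternatives, among them without FFD 3 (adjusted p 0.0117, range over the alternatives 0.00687 to 0.827).

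Genes reported in fatty liver inflammation and in liver progenitors rose, 13 of 19, and none fell (14 higher adjusted over the list alone, camera adjusted p 1.15e-17, adjusted p 0.107 with an estimated correlation). The tetraspanin Cd63 rose by 2.46 (SE 0.14), the calcium-binding protein S100a11 by 2.10 (SE 0.14), the membrane-binding annexin Anxa5 by 2.48 (SE 0.18) and the keratin Krt8 by 1.93 (SE 0.18). The list of lipid-associated and monocyte-derived macrophage markers rose in the same regions, 9 of 10 (9 higher and 1 lower adjusted over the list alone, camera adjusted p 4.04e-12, adjusted p 0.107 with an estimated correlation), and both lists hold Spp1. The lectin Clec7a rose by 1.90 (SE 0.18, under the detection limit in all NCD regions and 3.27 with background subtracted) and the tetraspanin Cd9 by 1.25 (SE 0.14), beside Mmp12. Kupffer cell and macrophage genes rose in 8 of 15 cases and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p 4.29e-06, adjusted p 0.323 with an estimated correlation), among them the protease Ctss at 1.21 (SE 0.15) and the complement genes C1qb at 1.03 (SE 0.16) and C1qa at 0.91 (SE 0.15). MHC class II genes rose in 6 of 10 cases (7 adjusted over the list alone, camera adjusted p 6.48e-07, adjusted p 0.323 with an estimated correlation), with H2-Aa at 2.03 (SE 0.19) and H2-Ab1 at 2.02 (SE 0.21). Stellate cell and fibroblast genes rose in 10 of 17 cases (11 adjusted over the list alone, camera adjusted p 1.69e-10, adjusted p 0.221 with an estimated correlation), and the matrix genes Bgn and Sparc rose by 1.74 (SE 0.21) and 1.35 (SE 0.16) beside the collagens.

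Markers of other cells did not all move that way, but most of these lists lay near background. Above the detection limit in all NCD regions were 12 of 14 endothelial, 3 of 10 lymphocyte, 2 of 7 neutrophil, 0 of 7 cholangiocyte and 2 of 4 erythroid genes. Genes at or under the limit in every region had a median of -0.33. Lists other than endothelium therefore do not settle whether those cells rose or fell. Endothelial genes gave 1 higher and 2 lower of 14 (1 and 3 adjusted over the list alone, camera adjusted p 0.473, adjusted p 0.847 with an estimated correlation), led by the nuclease Dnase1l3 at -0.96 (SE 0.19), and the list passed as lower without FFD 1 (adjusted p 0.0467) and with FFD 3 as the only FFD region (mean shift -0.27, adjusted p 0.0287). Lymphocyte genes gave 1 higher and 1 lower of 10 (1 and 3 adjusted over the list alone, camera adjusted p 0.379, adjusted p 0.725 with an estimated correlation), with the chemokine Ccl5 higher by 1.12 (SE 0.17) and Ms4a1 lower by 1.21 (edgeR adjusted p 0.000972). Neutrophil genes gave 0 higher and 2 lower of 7 (3 lower adjusted over the list alone, camera adjusted p 0.494, adjusted p 0.683 with an estimated correlation). Cholangiocyte genes rose in 3 of 7 cases (3 adjusted over the list alone, camera adjusted p 0.00807, adjusted p 0.485 with an estimated correlation), and that call was lost without FFD 2 (adjusted p 0.0722) and with FFD 3 as the only FFD region (0.780). Of 4 tested erythroid genes 1 was lower (1 adjusted over the list alone), too few for a list test.

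Acute phase genes rose in 11 of 25 cases and fell in 4 (11 and 5 adjusted over the list alone, camera adjusted p 1.53e-05, adjusted p 0.405 with an estimated correlation). Lcn2, Saa1, Saa2 and the plasma glycoprotein Orm2, at 2.42 (SE 0.17), were higher. The 4 that fell were Hamp, Fgb, Fga and Fgg, the iron hormone and the fibrinogen chains, at -1.77, -1.12, -0.87 and -0.83. With FFD 3 as the only FFD region Hamp stood at -3.12 and Fgb at -0.64 (adjusted p 0.150). NF-kB targets and chemokines rose in 6 of 15 cases and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p 2.03e-06, adjusted p 0.221 with an estimated correlation). The chemokine Cxcl16 rose by 0.99 (SE 0.13) and the adhesion molecule Vcam1 by 1.03 (SE 0.15, under the detection limit in all NCD regions and 2.32 with background subtracted). Class I antigen presentation genes rose in 5 of 14 cases (6 adjusted over the list alone, camera adjusted p 7.81e-06, adjusted p 0.221 with an estimated correlation), first H2-D1 at 0.98 (SE 0.16), whose target H2-L shares. Interferon response genes had 1 of 23 higher (0 adjusted over the list alone, camera adjusted p 0.000389, adjusted p 0.344 with an estimated correlation). Complement and coagulation genes gave 1 higher and 7 lower of 27 (1 and 7 adjusted over the list alone, camera adjusted p 0.246, adjusted p 0.794 with an estimated correlation), with coagulation factor F11 at -1.34 (SE 0.13) and complement C8b at -1.60 (SE 0.19), and the list passed as lower without NCD 1 (adjusted p 0.0187) or FFD 3 (0.0488). Beside these lists, 8 of 15 Kupffer cell genes and 9 of 10 lipid-associated macrophage genes were higher in the FFD regions (adjusted p 0.323 and 0.107 with an estimated correlation).

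Lysosome and autophagy genes rose in 8 of 21 cases and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p 2.97e-06, adjusted p 0.275 with an estimated correlation), among them the proteases Ctsb at 1.25 (SE 0.17) and Ctsd at 1.03 (SE 0.15), beside the 8 of 15 Kupffer cell genes (adjusted p 0.323 with an estimated correlation). NRF2 targets rose in 4 of 20 cases and 1 fell (5 and 2 adjusted over the list alone, camera adjusted p 0.00491, adjusted p 0.593 with an estimated correlation), first the glutathione peroxidase Gpx4, which reduces lipid peroxides, at 1.23 (SE 0.15). Cell death genes rose in 2 of 15 cases (2 adjusted over the list alone, camera adjusted p 0.0150, adjusted p 0.221 with an estimated correlation), first Mcl1, which restrains apoptosis, at 0.97 (SE 0.13). Genes of p53 and senescence rose in 3 of 16 cases (3 adjusted over the list alone, camera adjusted p 0.0226, adjusted p 0.221 with an estimated correlation), and this call was lost without NCD 3 (adjusted p 0.0890). Ribosomal protein genes had 1 higher and 1 lower of 25 (0 adjusted over the list alone, camera adjusted p 0.00874, adjusted p 0.683 with an estimated correlation), a call lost without FFD 2 (adjusted p 0.0920). Oxidative phosphorylation had 0 of 24 genes past the test with edgeR (3 at an unadjusted p under 0.05, 0 adjusted over the list alone), yet the list as a whole was higher (camera adjusted p 0.0147, adjusted p 0.721 with an estimated correlation). That call was lost without NCD 1 (adjusted p 0.152), NCD 2 (0.0803) or FFD 3 (0.140) and with NCD 1 and NCD 2 summed (0.0964).

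The other lists were not called by camera with the preset correlation, though fry called the clock list (fry adjusted p 0.0237). Iron and heme genes gave 2 higher and 2 lower of 17 (2 and 2 adjusted over the list alone, camera adjusted p 0.0895, adjusted p 0.323 with an estimated correlation), with Hamp, the iron hormone hepcidin, at -1.77 (SE 0.33, adjusted p 0.0790 with edgeR's robust option). The iron list passed as higher without a filter (adjusted p 0.00797), with filterByExpr (0.00796) and with FFD 3 as the only FFD region (0.0158). Clock genes gave 4 lower of 17 (6 adjusted over the list alone, camera adjusted p 0.0993, adjusted p 0.369 with an estimated correlation), with the repressor Nr1d1 at -0.79 (SE 0.13, adjusted p 0.0883 with negative probe scaling) and the list past the test without FFD 2 (adjusted p 0.0467). Hepatokine and growth factor genes gave 2 higher and 4 lower of 19 (2 and 5 adjusted over the list alone, camera adjusted p 0.841, adjusted p 0.960 with an estimated correlation), with Angptl8, which restrains lipoprotein lipase, at -1.99 (SE 0.18). Hepatocyte transcription factors gave 1 higher and 3 lower of 16 (1 and 3 adjusted over the list alone, camera adjusted p 0.546, adjusted p 0.792 with an estimated correlation), with the repressor Bcl6 at -1.31 (SE 0.18). The other lower members, Hnf4a and Foxa3, lost their calls under TMM (edgeR adjusted p 0.0703 and 0.117). Mitochondrial and peroxisomal biogenesis genes gave 1 higher and 1 lower of 14 (1 and 1 adjusted over the list alone, camera adjusted p 0.558, adjusted p 0.792 with an estimated correlation), with the peroxisome factor Pex11a at 0.77 (SE 0.14).

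Proteasome genes had 0 of 18 past the test with edgeR (1 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p 0.144, adjusted p 0.721 with an estimated correlation), and the list passed as higher without a filter (adjusted p 0.00940), with filterByExpr (0.00939), without NCD 3 (0.0318) or without FFD 2 (0.0467). ER stress genes gave 3 lower of 18 (3 adjusted over the list alone, camera adjusted p 0.808, adjusted p 0.960 with an estimated correlation). Of these, Hyou1 and Dnajb9 lost their calls under TMM (edgeR adjusted p 0.0615 and 0.0691). The integrated stress response gave 2 lower of 13 (1 higher and 2 lower adjusted over the list alone, camera adjusted p 0.495, adjusted p 0.721 with an estimated correlation). Both, Ddit3 and Phgdh, lost their calls under TMM (edgeR adjusted p 0.0817 and 0.0691). Cell cycle genes gave 2 higher and 1 lower of 16 (2 and 2 adjusted over the list alone, camera adjusted p 0.948, adjusted p 0.981 with an estimated correlation). Fatty acid synthesis, gluconeogenesis and biogenesis lists had medians under 0 (-0.04, -0.05 and -0.06) with mean shifts against the other genes above 0 (0.03, 0.08 and 0.07). The cell cycle list had a median of -0.13, a mean shift of 0.02 and a test pointing down, and the periportal list a mean shift of -0.11 with a test pointing up.

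**Figure D3:**
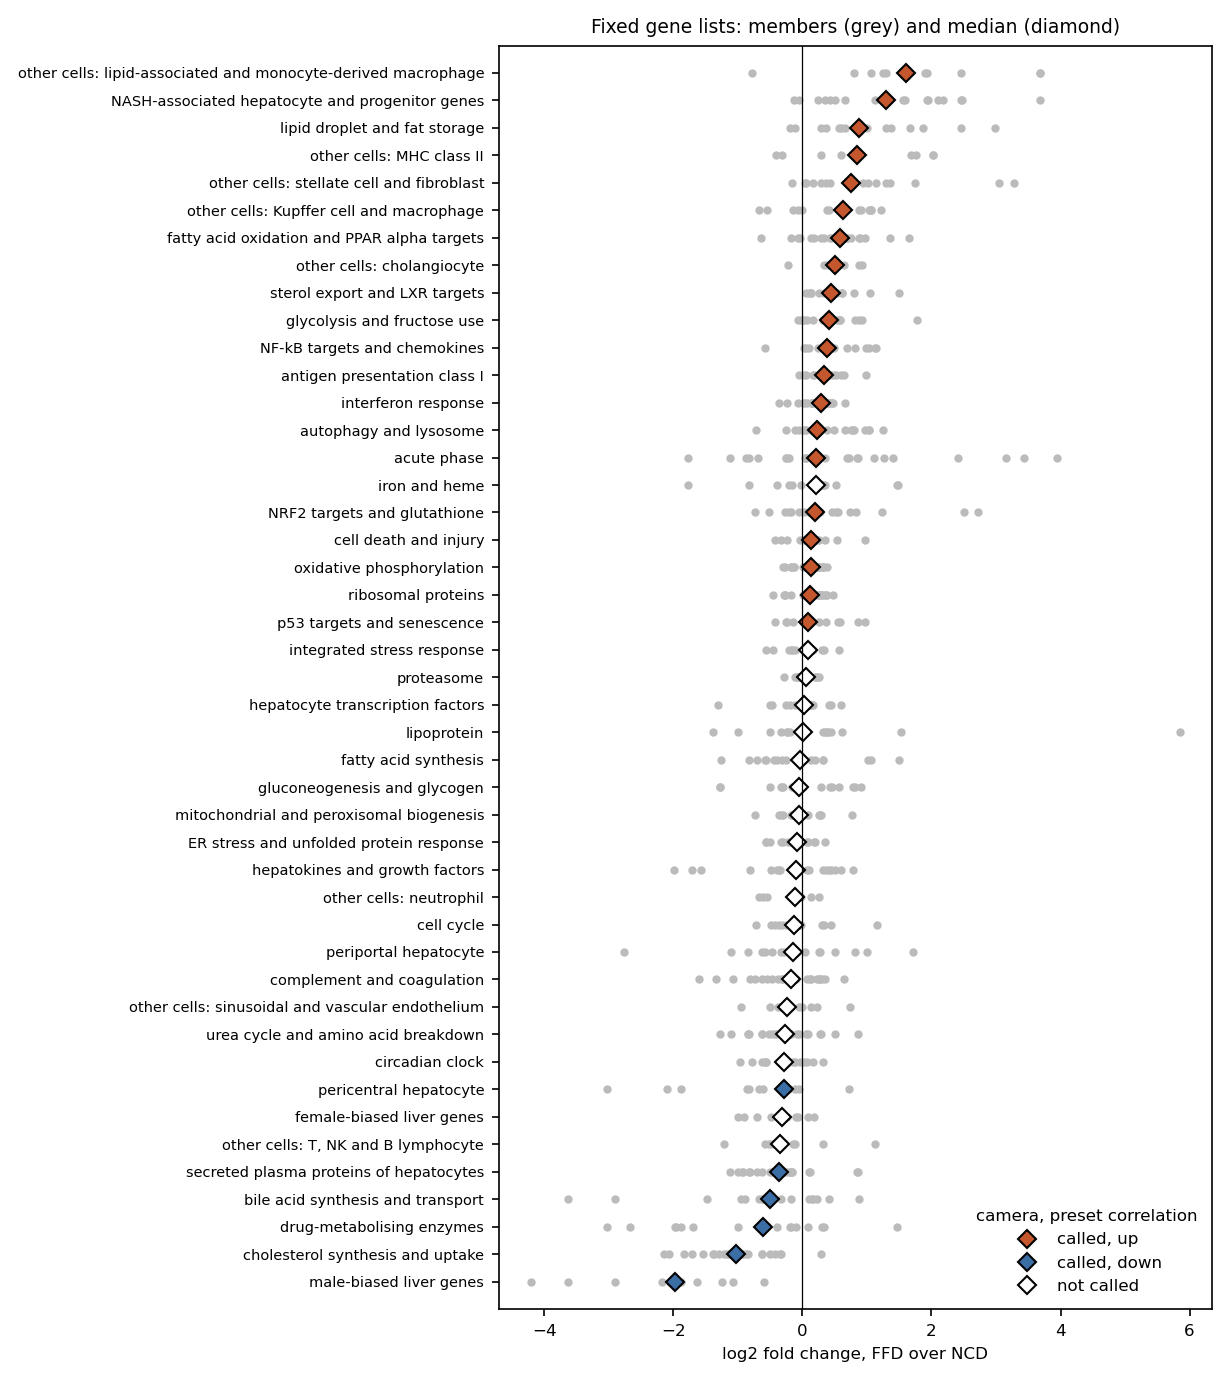
Log2 fold change (FFD over NCD) of every tested member (grey points) and the median (diamonds) of the 45 tested lists, coloured where camera with the preset correlation passed. The highest median, 1.60, belongs to the lipid-associated macrophage list and the lowest, -1.97, to the male-biased genes.

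In all, 20 lists were called higher and 6 lower with the preset correlation, and 0 with an estimated correlation (smallest adjusted p 0.107). A lost call does not by itself show correlated genes. The estimated setting also leaves camera only the residual degrees of freedom of 6 regions, which raises p. The loss of all calls is therefore no measure of correlation within the lists. The cell death list had an estimated correlation of 0.0093, below the preset 0.01, yet its unadjusted camera p went from 0.0080 to 0.0562. By its directional test fry called 15. Among list members 271 passed over all genes tested and 317 adjusted over the list alone. The 2237 called genes were part of 4345 with an unadjusted p under 0.05. The number of called genes was 1190 without NCD 1, 1013 without NCD 2 and 1413 without FFD 2. It was 1425 with NCD 1 and NCD 2, the closest pair of regions, summed as 1 sample.

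The balance of rises and falls moved with the scaling. The negative probes stood at -0.39 and the median gene at -0.11 on the scale used, and 242 of 2259 genes at or under the detection limit in every region were lower while 1 was higher. Under TMM the median gene stood at -0.01, with 1138 higher and 893 lower, and under negative probe scaling at 0.28, with 3632 higher and 206 lower. All 152 called genes that the naming rule picked kept their direction under each of these scalings.

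**Figure D4:**
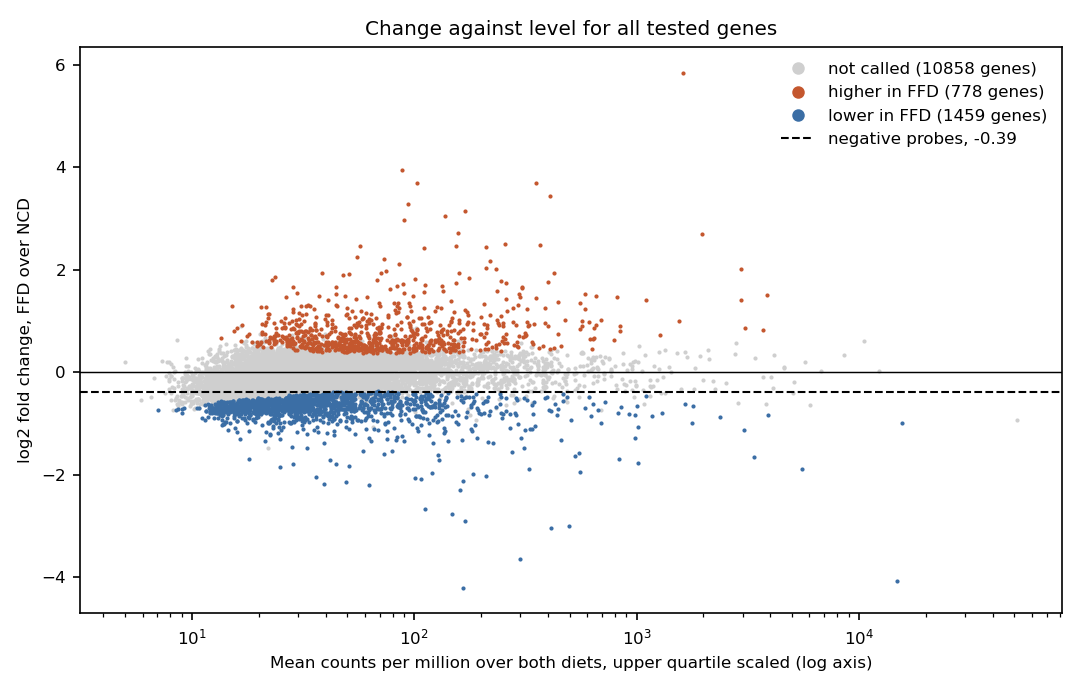
Log2 fold change (FFD over NCD) against mean CPM (log axis) for the 13095 tested genes, with the negative probes at -0.39 (dashed line). Called genes are coloured, 778 higher and 1459 lower.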

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

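Both comparisons in this part were chosen after the values had been seen, and no explanation was tested. A signal outside the comparisons was seen for the mCherry/tdTomato reporter target, which stood at 4.13 to 6.26 times the negative probe level over the 6 regions, where 10 other reporter targets stood at 0.520 to 1.34 times. The sum of target counts over the deduplicated reads of the segment table was 1.20 in FFD 1, 1.51 in FFD 2 and 1.01 in FFD 3, above the ratios of 0.996 to 0.997 in the NCD regions.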

How the results depend on the processing

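Summing NCD 1 with NCD 2 and keeping FFD 3 alone were chosen after the data were seen, as was the deposited limit of quantitation. Of the 24 leading genes 22 kept their calls under all 20 alternatives, and of 152 called named genes 90 did, with none of the 152 changing direction. Of 26 called lists 20 kept their calls in 15 settings other than the estimated correlation and fry. Without a filter and with filterByExpr the lipoprotein (adjusted p 0.00354 and 0.00353), iron (0.00797 and 0.00796) and proteasome lists (0.00940 and 0.00939) passed as higher and the secreted plasma list did not pass (0.138). Among genes above the detection limit in 3 regions the complement (0.0476) and urea cycle lists (0.0496) passed as lower, and oxidative phosphorylation (0.0999) and ribosomal proteins (0.0745) did not pass. Negative probe scaling added the female-biased (0.0444) and urea cycle lists (0.0179). Lower genes, 1459 as reported, numbered 893 under TMM, 894 under DESeq2 size factors and 604 under total counts. Negative probe scaling gave 3838 genes, 3632 higher and 206 lower, and turned Psma3 from -0.29 to 0.10. The DESeq2 Wald test called 1229 (467 lower, no adjusted p for 2793 genes), and background subtraction 1425 (503 lower). The threshold of 0.1 gave 3472 (2361 lower) by construction, and a log2 change over 1 gave 282 (162 and 120). With 1 region left out the ranges were 1013 to 2633 genes, 396 to 854 higher and 617 to 1779 lower. NCD 1 with NCD 2 as 1 sample gave 1425 (511 and 914). FFD 3 alone gave 817 (431 and 386), assumed to vary as the NCD regions do. Lists numbered 0 with an estimated correlation, 15 with fry and 25 to 28 with 1 region left out. Except where construction (a threshold, fewer samples) shows it, the cause was not tested. The gain of 1322 genes above the detection limit turned to -5.33 with a limit of 10 counts (exact p = 0.6), which nearly every gene passes, was 3235 with the deposited limit of quantitation and ranged from 789.7 to 1665 with 1 region left out. Alb passed as lower with the DESeq2 Wald test (adjusted p 0.00687), limma voom (0.0207), edgeR's robust option (0.0245) and without FFD 3 (0.0117), in a range of 0.00687 to 0.827.

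Mean shifts of these lists changed sign, and the cause was not tested. ER stress went from -0.03 to 0.0506 without a filter and with filterByExpr, and to 0.21 with FFD 3 alone. Endothelium went from -0.09 to 0.0071 without a filter and with filterByExpr. Fatty acid synthesis went from 0.03 to -0.0172 above the detection limit, to -0.0733 with NCD 1 and NCD 2 summed and to -0.13 with FFD 3 alone. The integrated stress response went from 0.09 to -0.0285 above the detection limit. With FFD 3 alone the secreted plasma list was at 0.0501, periportal at 0.43 (passing as higher, adjusted p 0.000775), urea cycle at 0.10 and cell cycle at -0.0930. With 1 region left out the ranges were -0.15 to 0.0377 for ER stress, -0.22 to 0.0049 for endothelium, -0.20 to 0.23 for fatty acid synthesis, -0.0074 to 0.17 for gluconeogenesis, -0.0126 to 0.12 for biogenesis, -0.13 to 0.12 for cell cycle and -0.38 to 0.0638 for periportal genes. In the simulation, with 200 planted changes, 37.3% of the 1.5-fold changes were recovered. In the real data, with 2237 called genes, some smaller changes passed, such as Ugt1a1 at -0.39 (edgeR adjusted p 0.0487). The simulated share therefore does not set the smallest change that could be called in the real data.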

Other observations

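Chosen after the results were seen were the tests of gene families and the genes named from them, and the tests of upper quartile scaling, of a lower hepatocyte share, of more macrophage RNA and of fewer pericentral hepatocytes. Genes were grouped by the letters of their symbol, and 148 families of at least 10 members were tested with camera at the preset correlation. Of these 5 were called higher and 11 lower, and 0 with an estimated correlation. Annexins, which bind membranes in the presence of calcium, rose in 7 of 10 cases and 1 fell (median 0.66, adjusted p 3.58e-07, adjusted p 0.451 with an estimated correlation). Beyond Anxa5 and Anxa2, Anxa4 rose by 1.07 (SE 0.16) and Anxa3 by 0.74 (SE 0.13). Carboxylesterases, which hydrolyse esters of drugs and lipids, fell in 6 of 13 cases and none rose (median -0.61, adjusted p 0.00177, adjusted p 0.705 with an estimated correlation). Ces2c fell by 1.45 (SE 0.20) and Ces1b by 0.92 (SE 0.14). UDP-glucuronosyltransferases, which conjugate drugs and bilirubin, fell in 8 of 13 cases (median -0.44, adjusted p 0.00366, adjusted p 0.705 with an estimated correlation), with Ugt2b35 at -0.98 (SE 0.15) and Ugt2b38 at -1.07 (SE 0.16). All 62 tested P450 genes together had 27 lower and 1 higher (median -0.53, adjusted p 1.36e-08, adjusted p 0.195 with an estimated correlation). Under negative probe scaling, where the median of all genes was 0.28, the medians were 1.06 for annexins, -0.23 for carboxylesterases, -0.06 for UDP-glucuronosyltransferases and -0.13 for P450 genes. Their signs also held under TMM and total counts. The same was true of the olfactory receptor family and of the Vmn family, at -0.09 and -0.18 under negative probe scaling. A kept sign therefore does not set the lower enzyme families apart from these 2 families.

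Olfactory receptor genes, not expressed in liver as far as is generally known, had 115 of 348 members lower and none higher (median -0.48, adjusted p 1.45e-16, adjusted p 0.705 with an estimated correlation), and 40 of them lay above the detection limit in all 6 regions. Their median was -0.38 under TMM, -0.36 under total counts and -0.09 under negative probe scaling. The families of Gpr and Zfp genes were called lower at medians of -0.36 and -0.23, and both medians turned positive under negative probe scaling (0.03 and 0.16).

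More genes fell than rose under upper quartile scaling, with 1.88 lower genes for each higher one. Genes at or under the detection limit in all regions had a median 0.0616 above the negative probes' log2 change of -0.39, so their falls are consistent with scaled background. Whether the excess comes only from targets near background cannot be told apart: among genes above the limit in at least 3 regions the ratio was 1.69 when they were scaled and tested alone (1.35 to 2.04 with 1 region left out) and 1.40 on the original scale, on both sides of the bound of 1.5 that was set, while background subtraction gave 922 higher and 503 lower. The scale itself may set the excess, since the ratio was at most 0.790 under TMM, DESeq2 size factors and total counts. A change of diet that lowers many transcripts was not separable from this by any test run.

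Macrophage and stellate cell genes were higher in FFD regions, although the regions were chosen by Albumin and not marked by CLEC4F. A lower share of hepatocyte RNA that raises every other cell type alike would raise these lists equally. The median of the lipid-associated macrophage list (10 genes) lay 1.85 on the log2 scale above that of the endothelial list (14 genes, median -0.25). The gap argues against an equal rise for these 2 lists only, which were picked after the results were seen. Its permutation p was 0.00055 over 100000 resamples. That test exchanged genes as if independent, though the estimated correlations within the lists were 0.12 and 0.52. The p is therefore no measure over regions and adds no weight. More macrophage RNA in the FFD regions stays open and cannot be told apart from the other explanations, since the 100% of the 5 most abundant Kupffer cell and macrophage genes that were higher, C1qa, C1qb, C1qc, Cd5l and Ctss, are part of the pattern itself. Of the 15 Kupffer cell genes 14 lay above the limit in all NCD regions and 0 were in another list, and of the 10 lipid-associated macrophage genes 3 lay above it and 1, Spp1, was in another list. Whether the RNA came from more cells, from other cells overlying the chosen areas or from hepatocytes expressing these genes on FFD stays open and was not tested.

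Male-biased liver genes were lower in FFD. Animals of different sex in the diets were argued against by the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, whose median was -0.16, with 0 of 4 lower past the threshold by edgeR and Uty nearest at an adjusted p of 0.0513. Uty lay under the detection limit in all 6 regions, at 1.23 to 1.90 times the negative probe level, so it says little here. Xist, which the prediction also named, was not among the measured targets. Eif2s3y stood at 5.76 to 8.43 times the negative probe level in all 6 regions. Fewer pericentral hepatocytes in the FFD regions might lower part of these genes. The 12 pericentral markers that are not P450 genes had a median of -0.28 (median absolute deviation 0.17), with 3 lower and 1 higher. As a part, the explanation cannot be told apart from a change within the cells because that median lies between the values set for either outcome. The male-biased list had a median of -1.97 and all tested genes -0.11 on the same scale. A loss of the size seen in these 12 markers would thus cover only a small part of the fall. An effect of the diet on hormone-regulated transcription stays open and was not tested.

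The 6 regions can be split into 3 and 3 in 10 ways, too few for a share under 0.05. By genes, 1 of 10 splits reached 2237, the real one, and the highest of the others was 0 with edgeR (147 to 801 genes at an unadjusted p under 0.05, and 0 with limma trend). Every other split mixes the diets within both groups, so a difference between the diets widens the spread there and lowers the calls. The 0 is therefore no measure of chance. By lists, 3 of 10 splits reached 26 with the preset correlation, and the highest of the others was also 26. The other splits with 26 lists set NCD 1 and NCD 2 with FFD 1, and NCD 1 and NCD 2 with FFD 2, against the rest. Part of the diet contrast stays in each of the other splits, so they are no null for the lists. The number of lists called at the preset correlation thus did not set the real split apart, and no conclusion on diet follows from it.

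NCD 1 and NCD 2 were closer than any other pair within a diet. Their counts differed with a chi-square per degree of freedom of 1.27, against 5.13 to 7.89 for the other within-diet pairs, and they lay 2258 scan units apart on the slide, against 7158 to 18704. The unit of the scan positions is not stated, and the NCD and FFD regions lay in separate parts of the slide. The labels do not tie a region to a mouse, so whether these are 2 of the 3 NCD mice was not settled. With both summed as 1 sample, 1425 genes were called in place of 2237.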
